A study of Mus musculus with 34 samples.

How the data were processed

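Dorsal root ganglia were removed, frozen and extracted by the authors, and libraries of total RNA were prepared after depletion of ribosomal RNA and sequenced on a NextSeq500. Each of the 17 mice has 2 sets of reads in the labels, whose codes name lanes of the same mouse, so they were treated as 2 runs of 1 library and never as replicates. A chi-square per degree of freedom between the 2 sets of a mouse was 1.02 to 1.07 in the Aged mice. In the Old mice it was 1.71 to 1.77, so their 2 sets differed by more than sampling of reads would give. The reason was not tested. The authors aligned the reads to the mouse genome (GRCm38, mm10, per their processing notes); the aligner and the strandedness of counting are not given in the sources used here. The deposited count table gives raw read counts per gene and run for 36926 genes, of which 8 are empty in every run. The deposited RPKM table gives 1 value per mouse on a linear scale for 22861 genes, selected by the authors by a rule that is not stated. Symbols, Entrez numbers and positions came from the deposited gene table, and 21552 of these genes were found by Entrez number in a reference gene table of the same build, 8542 of them (39.6%) with the same start and end.

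The count table was checked against the RPKM table before either was used. The reads of the 13 mitochondrial protein genes and their RPKM gave an implied depth per mouse, with a coefficient of variation over these genes of 0.197% to 0.923%. At that depth the count table held a median of 1.52% of the implied reads over 13970 well-expressed genes, under 10% for 9841 genes (70.4%), and no read at all for 1896 genes. It held 99.9% for Malat1, 26.1% for Pink1, 2.79% for Snca and 1.32% for Mpz. The count table is therefore partial, and which features it covers is not stated. An edgeR test on counts summed over runs had been planned as the main test. Since these counts miss most reads of most genes, the main test became limma on log2(RPKM + 1), which had been planned as an alternative, and this exchange was made after the files were seen. The 2 routes gave 3381 (limma on RPKM) and 1050 (edgeR on partial counts) genes for the genotype effect over both ages, with 830 in common.

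The main model used limma 3.58.1 in R 4.3.3 with a trended prior variance, a pseudocount of 1, a mean for each of the 4 groups of genotype and age class, and all 22861 genes. The 4 groups held 4 wildtype Old, 4 wildtype Aged, 4 double mutant Old and 5 double mutant Aged mice. The contrasts were double mutant against wildtype over both ages (the mean of the differences within age classes), within Old, and within Aged, Old against Aged within each genotype, and the difference between the genotype effects. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. Fold changes refer to RPKM + 1, which shrinks the change of genes with low values. No reading of RPKM can give counting error per gene, so the precision of each value is given by the spread between mice.

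The choice of tests, gene lists and named genes was written down before the data were examined. Named genes were Pink1, Snca, Prnp and Xist. They also included up to 10 genes per direction with the largest absolute log2 fold change among those that passed for the genotype effect over both ages, and up to 5 per direction for every other contrast. A mean of at least 1 was required, planned as CPM and applied to RPKM, and symbols of predicted genes starting with Gm, ending in Rik or holding -ps were left out. Where fewer than 3 genes passed in a direction, the 5 with the smallest p are given as values. From each gene list described, up to 4 members with the smallest p were named. The 53 lists covered pathways, protein complexes, types of sensory neuron, other cells of the ganglion and tissues that could adhere to it, and 1261 of their 1275 members were measured. Lists were tested with camera (limma, two-sided, preset correlation of 0.01 between genes, Benjamini-Hochberg over lists), and again with an estimated correlation and with fry, which asks if a list's genes move on balance one way. Members that passed were counted over all genes tested and again adjusted over the list alone.

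Simulated changes were used to test the steps. Of 200 genes raised or lowered by 0.5 on the log2 scale among 22861, limma recovered 97% over both ages, 88.5% in Old and 91% in Aged mice, with 8, 20 and 14 false calls. At a log2 change of 1 it recovered 99%, 97% and 99%, with 11, 10 and 9 false calls. The changed genes were drawn from those with a mean RPKM of at least 1, and the noise was independent between genes. These rates therefore do not cover genes with lower values, smaller changes or shifts that many genes share.

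Alternatives on RPKM were a pseudocount of 0.1, only genes with a mean RPKM of at least 1, only the groups compared, age in 3 classes, no age term, a block for mouse number, 1 surrogate variable (sva 3.50.0) and each mouse left out in turn. Those on counts were edgeR 4.0.16 with TMM or RLE factors, with no low-count filter and with each run alone, limma-voom, and DESeq2 1.42.0. After seeing the data, rescaling by TMM factors, centring on the median, leaving out genes under 300 bases and a covariate of myelinating Schwann cell markers were added. Other splits of the mice into groups of the same sizes, all or 100 drawn at random, were fitted in the same way. The read totals per run and the partial counts were not used for fold changes in the main comparisons.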

Results

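Dorsal root ganglia hold the cell bodies of sensory neurons together with satellite glia, Schwann cells, vessels and connective tissue. Total RNA depleted of ribosomal RNA was sequenced from the ganglia of 17 untreated female mice. A group of 9 mice lacked Pink1, which encodes a mitochondrial kinase needed for mitophagy, and carried a mutant SNCA transgene, which encodes alpha-synuclein. These double mutants model Parkinson's disease, and 8 wildtype mice of the FVB.Sv129 background served as controls. The mice fell into the age classes Old (87 to 90 weeks, 4 wildtype and 4 double mutant mice) and Aged (41 to 62 weeks, 4 wildtype and 5 double mutant mice). The series asked how the transcriptome of the ganglia differs between the genotypes from middle to old age.

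The deposited count table held between 8.91 and 10.7 M reads per Old mouse and between 4.62 and 6.03 M per Aged mouse. It covered only part of the reads, since the deposited RPKM values and the reads of the 13 mitochondrial protein genes implied 49.6 to 57.5 M reads per Old mouse and 24.2 to 32.6 M per Aged mouse. The comparisons below therefore used the deposited RPKM of 22861 genes on a log2 scale. The ratio of reads in the first to the second run was 1.01 to 1.02 in the Old mice and 1.05 to 1.06 in the Aged mice, so the age classes also differed in how they were sequenced. All values per gene are for the GRCm38 (mm10) build. Over 13929 genes with a mean RPKM of at least 1, the first principal component held 23.7% of the variance and placed every wildtype mouse below 0 and every double mutant mouse above 0. The second held 17.6% and placed every Aged mouse below 0 and every Old mouse above 0.

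**Figure D1:**
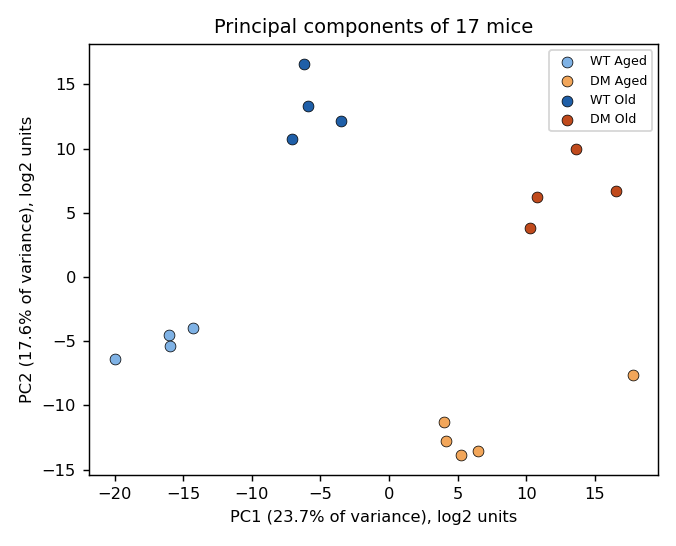
Each point is 1 of the 17 mice, placed by its scores on the first (x axis, 23.7% of the variance) and second (y axis, 17.6%) principal component of log2(RPKM + 1), in log2 units. The genotypes separate along the first component and the age classes along the second.

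The genes named in the labels were examined first. Pink1 (chromosome 4, 138313409 to 138326296) fell from 126 ± 9.01 RPKM in wildtype mice (SD, n = 8) to 7.81 ± 0.490 in double mutant mice (SD, n = 9), a log2 fold change of -3.84 ± 0.039 (SE, limma adjusted p = 1.62e-18). Snca (chromosome 6, 60731573 to 60829855) rose from 11.4 ± 0.930 RPKM (SD, n = 8) to 21.7 ± 10.2 RPKM (SD, n = 9), a log2 fold change of 0.74 ± 0.19 (SE, limma adjusted p = 0.0142), and all 9 double mutant mice lay above the wildtype range. Its level varied among the double mutants. It was 14.0 to 14.2 RPKM in the 2 mice of 41 weeks, 22.6 to 41.3 in the 3 mice of 60 weeks and 13.4 to 20.4 in the 4 Old mice. Prnp, which encodes the prion protein, was at 141 ± 5.24 RPKM (SD, n = 8) in wildtype and 137 ± 10.8 RPKM (SD, n = 9) in double mutant mice (limma adjusted p = 0.432). Xist, which is expressed from the inactive X chromosome, was at 21.5 RPKM in both genotypes and was present in every mouse, as the labels' sex requires, and it stood at a log2 fold change of -0.18 with edgeR on the partial counts (adjusted p = 0.0273). Transgene reads count towards mouse Snca only as far as they align there, and the number of reads for Snca in the count table was 2.79% of that implied by its RPKM. On these partial counts the rise of Snca did not pass without a low-count filter, with either run alone or in DESeq2 (adjusted p of 0.102 to 0.220).

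**Figure D2:**
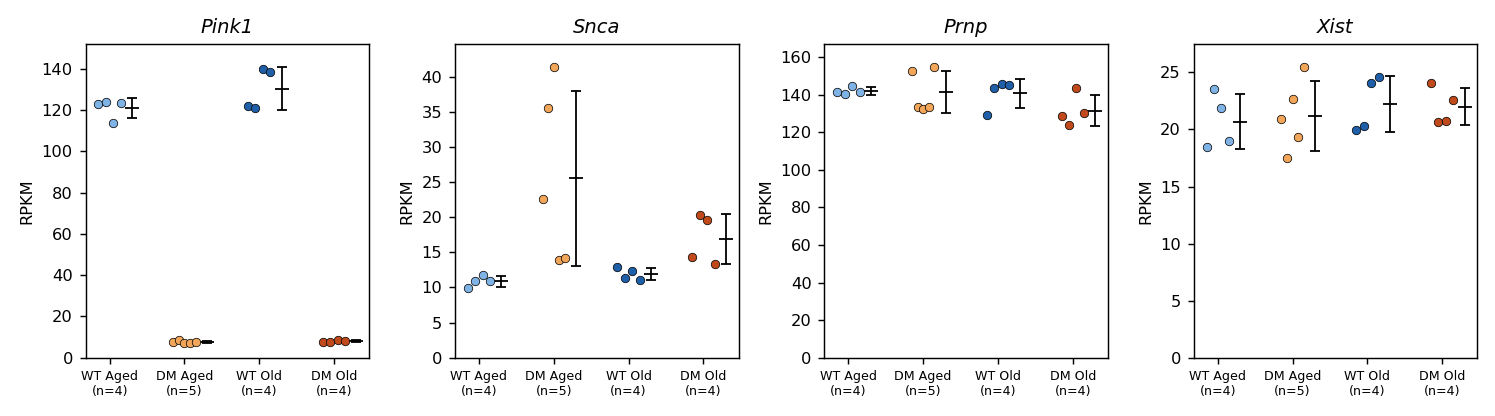
RPKM (y axis) of Pink1, Snca, Prnp and Xist in each mouse (points), with the mean and SD of each genotype and age class beside them (n = 4 or 5). Pink1 lies between 6.96 and 8.47 RPKM in the double mutant mice and between 114 and 140 RPKM in the wildtype mice.

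The comparison of the genotypes over both ages asked which transcripts differed between 9 double mutant and 8 wildtype mice when the difference was averaged over the age classes. Besides Pink1, the genes that fell most included Psmc3ip, a partner of the meiotic recombinases (8.91 ± 2.61 to 1.18 ± 0.259 RPKM), and Tekt2, a tektin of cilia and sperm flagella (4.96 ± 2.50 to 0.615 ± 0.147 RPKM). Fgf1, which encodes acidic fibroblast growth factor, fell from 108 ± 47.5 to 31.3 ± 1.57 RPKM. Folh1, the glutamate carboxypeptidase that hydrolyses N-acetylaspartylglutamate, fell from 24.0 ± 2.35 to 9.07 ± 1.11 RPKM, and the zinc-finger gene Zfp949 fell from 23.3 ± 1.78 to 8.77 ± 0.451 RPKM. Among the genes that rose most were the serine protease inhibitors Serpina3i (4.70 ± 4.35 to 17.7 ± 1.09 RPKM) and Serpina3f (2.01 ± 1.57 to 7.23 ± 0.554 RPKM) and the chemokine Ccl27a (1.28 ± 0.190 to 7.84 ± 0.526 RPKM). Lypd1, a membrane-anchored modulator of nicotinic receptors, rose from 2.04 ± 0.610 to 8.26 ± 3.28 RPKM, and Dnase1l3, a secreted nuclease that degrades chromatin, rose from 1.52 ± 0.331 to 6.21 ± 0.999 RPKM. These errors are SDs over 8 wildtype and 9 double mutant mice.

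The log2 fold changes of these genes, with their SEs, were 2.09 ± 0.24 for Serpina3i, 1.95 ± 0.054 for Ccl27a, 1.60 ± 0.15 for Serpina3f, 1.52 ± 0.19 for Lypd1 and 1.51 ± 0.092 for Dnase1l3. They were -2.14 ± 0.13 for Psmc3ip, -1.72 ± 0.22 for Tekt2, -1.54 ± 0.32 for Fgf1, -1.32 ± 0.071 for Folh1 and -1.32 ± 0.036 for Zfp949. Their limma adjusted p ran from 5.33e-13 for Ccl27a to 0.00397 for Fgf1. All 9 double mutant mice lay outside the wildtype range for each of these genes except Tekt2, with 3 mice outside, and Fgf1, with 1 mouse outside. Serpina3g, a neighbour of Serpina3i and Serpina3f that the rule did not choose here, moved the other way. It fell from 42.3 to 13.5 RPKM in the Aged mice and from 32.9 to 17.5 RPKM in the Old mice. The other transcripts chosen by the same rule were mostly small or of uncertain assignment. Mir7019 rose by 4.42 ± 0.28 on the log2 scale. It spans bases 138316132 to 138316200 of chromosome 4, within Pink1 and on the same strand, directly beside exon 6 (138316004 to 138316131). Whether its reads came from the microRNA or from other sequence of the targeted gene was not tested. The transcript AA465934 rose by 3.06 ± 0.44, Mir6982 by 1.54 ± 0.42, LOC105244693 by 1.47 ± 0.21 and Mir1291 by 1.24 ± 0.31. The predicted genes LOC101055754, LOC105244835, LOC100861615 and LOC102638110 changed by -1.84 ± 0.048, -1.46 ± 0.20, -1.41 ± 0.033 and -1.29 ± 0.075. All of these passed the test, with limma adjusted p of at most 0.0225. All 9 double mutant mice lay outside the wildtype range for each of them except Mir6982, with 7 mice outside, LOC105244693, with 5, and Mir1291, with 0. Mir1291 was at 0.186 and 4.07 RPKM in wildtype and double mutant Old mice and at 5.88 and 6.50 RPKM in the Aged mice. Its call ended with no age term, with the block for mouse number, with 1 surrogate variable and with the Schwann cell covariate (adjusted p of 0.0526 to 0.138), and that of Mir6982 with the last 2 of these (0.0704 and 0.157). On the partial counts Mir1291 stood at 0.45 in edgeR with no low-count filter and at 0.48 in DESeq2, without passing (adjusted p = 0.777 and 0.775).

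In total, 1652 genes rose and 1729 fell among the 22861 tested, with a median absolute log2 fold change of 0.19. This balance turned with the scaling, to 1930 and 1472 after centring on the median and 1798 and 1568 after TMM rescaling, both chosen after the data were seen. A fold change of at least 2 in RPKM + 1 was seen for 26 genes that rose and 42 that fell. The partial counts gave 539 genes that rose and 511 that fell in edgeR (10879 genes), in which Fgf1 stood at a log2 fold change of 0.044 and Folh1 at -0.22 without passing, and a block for mouse number gave 985 and 1021. With the mean of the myelinating Schwann cell markers as a covariate, chosen after the data were seen, 869 genes rose and 770 fell, of which 1467 in all were among the 3381. Of the 10 lists that passed camera with this covariate, 2 were among the 10 that passed without it. The covariate is itself the mean of a tested list and differed between the genotypes, at 4.51 in double mutant and 4.94 in wildtype Aged mice. Adjusting for it can therefore remove genotype effects whatever their cause.

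Several markers of connective tissue and myelin fell in the double mutant ganglia. Of 25 fibroblast and extracellular matrix genes 10 fell, none rose and 15 did not pass, among them the collagen genes Col6a3 (-0.56 ± 0.092), Col5a2 (-0.32 ± 0.074), Col5a1 (-0.37 ± 0.086) and Col6a1 (-0.55 ± 0.14; log2 fold change ± SE). The list's camera adjusted p was 2.41e-05 (adjusted p = 0.943 with an estimated correlation), and 16 members fell when adjusted over the list alone. Of 20 myelinating Schwann cell markers 8 fell and 12 did not pass, including the myelin genes Pmp2 (-1.03 ± 0.23), Pmp22 (-0.33 ± 0.093) and Mag (-0.34 ± 0.098) and the connexin gene Gjc3 (-0.20 ± 0.055). The camera adjusted p was 2.41e-05 (adjusted p = 0.943 with an estimated correlation), and 14 members fell when adjusted over the list alone. Of 13 pericyte and smooth muscle markers 5 fell, over all genes and adjusted over the list alone, with Notch3 at -0.28 ± 0.055, Cspg4 at -0.28 ± 0.057, Kcnj8 at -0.26 ± 0.060 and Pdgfrb at -0.33 ± 0.083. For pericyte and smooth muscle markers, camera gave an adjusted p of 0.00581 (adjusted p = 0.943 with an estimated correlation). With the Schwann cell covariate the fibroblast and pericyte lists did not pass camera (adjusted p = 0.509 and 0.642). The mean log2 value of the myelinating Schwann cell markers was 4.51 ± 0.188 in double mutant Aged mice (SD, n = 5) and 4.94 ± 0.169 in wildtype Aged mice (SD, n = 4). In the Old mice it was 4.70 ± 0.247 and 4.91 ± 0.294 (SD, n = 4 each). That of the fibroblast markers was 3.32 ± 0.199 and 3.89 ± 0.176 in the Aged mice and 3.32 ± 0.289 and 3.45 ± 0.388 in the Old mice, in the same order. In both Old groups the mouse lowest in the Schwann cell mean was also lowest in the fibroblast mean. These were wildtype mouse 3 (4.49 and 2.98) and double mutant mouse 4 (4.41 and 2.90). In the Aged groups the lowest mice differed. The lists therefore need not be separate changes, and whether the tissue make-up of the ganglia differed between mice was not tested.

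Some markers of large-diameter neurons, chaperones and enzymes of cholesterol synthesis rose by small amounts, while most members of these lists did not pass. Of 19 markers of large-diameter neurons, the A-fibre cells of touch and proprioception, 4 rose and 1 fell, over all genes and adjusted over the list alone. The potassium channel gene Kcnc1 rose by 0.25 ± 0.031, the calcium-binding protein gene Calb1 by 0.35 ± 0.063 and the calcium sensor gene Vsnl1 by 0.19 ± 0.043, whereas Necab2 was at -0.24 ± 0.072. For large-diameter neuron markers, camera gave an adjusted p of 0.0202 (adjusted p = 0.943 with an estimated correlation). Of 30 heat shock proteins and chaperones 4 rose, 6 when adjusted over the list alone, with Dnajb4 at 0.30 ± 0.033, Hspa2 at 0.32 ± 0.045, Dnajb1 at 0.31 ± 0.049 and Hspb8 at 0.086 ± 0.023. For chaperones, camera gave an adjusted p of 0.0213 (adjusted p = 0.943 with an estimated correlation). Of 26 genes of cholesterol biosynthesis 6 rose and 1 fell, and 13 rose and 3 fell when adjusted over the list alone. Cyp51, the lanosterol demethylase, rose by 0.26 ± 0.042 and the sterol reductase gene Dhcr24 by 0.17 ± 0.051, and Dhcr7, the last enzyme of the pathway, stood at -0.25 ± 0.070. For cholesterol synthesis, camera gave an adjusted p of 0.0246 (adjusted p = 0.943 with an estimated correlation). Of 9 mast cell markers 2 rose, also adjusted over the list alone, the IgE receptor genes Fcer1a (0.20 ± 0.034) and Ms4a2 (0.16 ± 0.047; camera adjusted p = 0.0341; adjusted p = 0.943 with an estimated correlation).

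Of 17 senescence genes 3 fell, 5 when adjusted over the list alone, and these were Glb1, which encodes the lysosomal beta-galactosidase (-0.24 ± 0.028), Igfbp3 (-0.58 ± 0.12) and Igfbp7 (-0.38 ± 0.090; camera adjusted p = 0.0354; adjusted p = 0.943 with an estimated correlation). The 77 ribosomal protein genes had a median log2 fold change of -0.06 (camera adjusted p = 0.0354; adjusted p = 1 with an estimated correlation). Among them 5 rose and 3 fell, or 2 and 2 when adjusted over the list alone, and Rps3a1 (0.76 ± 0.071) and Rpl35a (0.83 ± 0.11) moved against Rpl15 (-0.30 ± 0.036) and Rpl28 (-0.17 ± 0.036). Of 31 proteasome genes Psmc1 rose by 0.10 ± 0.027 and Psmc4 fell by 0.096, over all genes and adjusted over the list alone (camera adjusted p = 0.0361; adjusted p = 0.943 with an estimated correlation), and the call was lost after rescaling by TMM factors (0.0736).

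The lists closest to the genotype showed few changes apart from the engineered genes. Of 23 genes linked to Parkinson's disease only Pink1, Snca and Vps13c passed, over all genes and adjusted over the list alone, and Vps13c, a lipid transfer protein gene, fell by 0.32 ± 0.057 on the log2 scale (camera adjusted p = 0.504). Of 41 genes of mitophagy and autophagy none rose and 2 fell, Wipi2 (-0.05 ± 0.015) and Wipi1 (-0.15 ± 0.047), and none passed when adjusted over the list alone (camera adjusted p = 0.999). None of the 13 mitochondrially encoded protein genes passed in limma, with 0 at an unadjusted p under 0.05 and 0 of 13 past edgeR on the partial counts (camera adjusted p = 0.581). Of 36 nuclear genes of respiratory complex I 1 fell, Ndufb7 (-0.15 ± 0.039; camera adjusted p = 0.423), and of 40 genes of complexes II to V 2 rose and 2 fell, with Atp5o at 0.21 ± 0.051 and Atp5h at -0.16 ± 0.049 (camera adjusted p = 0.919). Adjusted over the list alone, 0 genes of complex I passed, and 1 of the other complexes rose and 1 fell.

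The genotypes were then compared within each age class, to ask whether the difference was alike at both ages. In the Old mice (4 against 4) 551 genes rose and 531 fell, and in the Aged mice (5 against 4) 911 rose and 1126 fell. Of these, 312 rose at both ages and 364 fell at both ages, where 21.96 and 26.2 would be shared if the calls were independent, and 1 gene passed in opposite directions. Across all 22861 genes the log2 fold changes of the age classes, which share no mouse, correlated with a Pearson r of 0.638 and a Spearman rho of 0.463, and 64.8% had the same sign. On the partial counts r was 0.652 with edgeR, over 10879 genes, but 0.230 with DESeq2, over 27368 genes with no low-count filter, where rho was 0.163 and 50.3% had the same sign. Genes are not independent replicates, so these values were set against 100 regroupings of the genotypes within each age class, which gave a Pearson r between -0.531 and 0.447. Pink1 stood at -3.85 in Old and -3.83 in Aged mice, Psmc3ip at -2.22 and -2.06, and the predicted gene LOC101055754 at -1.75 and -1.93. Mir7019 stood at 4.03 and 4.82 and AA465934 at 2.87 and 3.25.

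Further genes with the largest changes in the Old mice were Ccl27a (1.93 ± 0.078), Dnase1l3 (1.55 ± 0.13), Mir1291 (2.05 ± 0.45), Mir344b (-1.75 ± 0.39) and LOC102638110 (-1.42 ± 0.11; log2 fold change ± SE). In the Aged mice they were Serpina3i (2.84 ± 0.34), Serpina3f (2.18 ± 0.21), LOC105244693 (2.09 ± 0.29), Tekt2 (-2.20 ± 0.30) and LOC105244835 (-1.60 ± 0.27). In the wildtype mice Serpina3i was at 1.60 ± 0.368 RPKM in the Aged class and 7.79 ± 4.30 RPKM in the Old class (SD, n = 4 each). Partial counts in edgeR gave 383 genes in the Old and 519 in the Aged mice, and a fit of the 8 Old mice alone gave 476 genes. In the Aged mice 44.7% of the genes that passed had risen, and this was 60.1% after centring each mouse on its median, so the balance of rising and falling genes depended on the scaling.

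**Figure D3:**
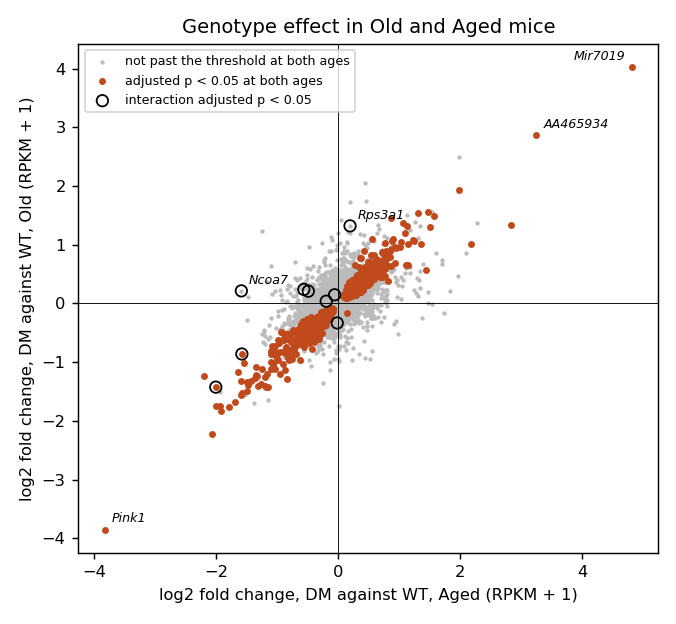
Each point is 1 of 22861 genes, with its log2 fold change of double mutant against wildtype in the Aged mice (x axis, 5 against 4) and in the Old mice (y axis, 4 against 4), from log2(RPKM + 1). Genes past an adjusted p of 0.05 at both ages are coloured and run along the diagonal, from Pink1 at -3.83 and -3.85 to Mir7019 at 4.82 and 4.03, and rings mark the 9 genes whose genotype effect differed between the ages.

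In the Aged mice several connective tissue and myelin markers fell, as in the pooled comparison. Of 25 fibroblast and matrix genes 7 fell, 19 when adjusted over the list alone, with Col6a3 at -0.63 ± 0.13 and Col6a1 at -0.82 ± 0.19. For the fibroblast list, camera gave an adjusted p of 3.18e-08 (adjusted p = 0.653 with an estimated correlation). Of 20 myelinating Schwann cell markers 4 fell, 12 adjusted over the list alone, with the myelin gene Plp1 at -0.44 ± 0.11 and the dystroglycan partner gene Drp2 at -0.67 ± 0.18. For the Schwann cell list, camera gave an adjusted p of 1.33e-06 (adjusted p = 0.653 with an estimated correlation). Of 16 endothelial markers 4 fell, 8 adjusted over the list alone, with the VEGF receptor gene Kdr at -0.42 ± 0.083 and Esam at -0.46 ± 0.11. For endothelial cells, camera gave an adjusted p of 0.00166 (adjusted p = 0.653 with an estimated correlation). Of 13 pericyte and smooth muscle markers 4 fell, 6 adjusted over the list alone (camera adjusted p = 0.00021; adjusted p = 0.653 with an estimated correlation), and of 12 meningeal markers 2 fell, by either adjustment (camera adjusted p = 0.00166; adjusted p = 0.653 with an estimated correlation). Of 33 oxidative stress genes and NRF2 targets 1 rose and 7 fell, over all genes and adjusted over the list alone, with the glutathione transferase gene Gsta4 at -0.59 ± 0.085 and the thioredoxin reductase gene Txnrd1 at -0.34 ± 0.069. For NRF2 targets, camera gave an adjusted p of 0.0225 (adjusted p = 0.653 with an estimated correlation). Of the 77 ribosomal protein genes 1 rose and 10 fell, or 1 and 26 adjusted over the list alone, with Rpl35a at 0.86 ± 0.15 and Rpl15 at -0.34 ± 0.049. For ribosomal proteins, camera gave an adjusted p of 6.91e-09 (adjusted p = 0.8 with an estimated correlation). Some neuronal genes rose. Of 19 large-diameter neuron markers 4 rose, 9 adjusted over the list alone, with Calb1 at 0.48 ± 0.087. For these neurons, camera gave an adjusted p of 2.28e-06 (adjusted p = 0.454 with an estimated correlation). Of 41 synaptic vesicle genes 5 rose, or 7 with 1 that fell adjusted over the list alone, with the vesicle protein gene Sv2b at 0.33 ± 0.051 and Syn2 at 0.19 ± 0.039. For synaptic vesicle genes, camera gave an adjusted p of 9.68e-05 (adjusted p = 0.653 with an estimated correlation). In the same mice the mean log2 value of the myelinating Schwann cell markers was 4.51 in double mutants and 4.94 in wildtypes, and with it as a covariate 962 genes passed in place of 2037.

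In the Old mice the interferon-stimulated genes and the macrophage and mast cell markers were higher as lists by camera with a preset correlation. Of 40 interferon-stimulated genes 2 rose, over all genes and adjusted over the list alone, Ifi35 by 0.54 ± 0.11 and the signalling gene Stat2 by 0.40 ± 0.10, while the antiviral gene Ifit1 was at 1.20 ± 0.35 without passing (limma adjusted p = 0.0679). The list's camera adjusted p was 0.000159 (adjusted p = 0.978 with an estimated correlation). Of 21 macrophage markers none passed in limma, nor when adjusted over the list alone, with 6 higher at an unadjusted p under 0.05 and 0 of 11 past edgeR. The complement genes C1qb and C1qc were at 0.75 ± 0.26 and 0.57 ± 0.20. For macrophages, camera gave an adjusted p of 0.0246 (adjusted p = 0.978 with an estimated correlation). Of 9 mast cell markers 2 rose, also adjusted over the list alone, Fcer1a by 0.29 ± 0.049 and Ms4a2 by 0.30 ± 0.069. For mast cells, camera gave an adjusted p of 0.0246 (adjusted p = 0.978 with an estimated correlation). Of 26 cholesterol synthesis genes 2 rose, 3 adjusted over the list alone, Ebp by 0.23 ± 0.054 and Cyp51 by 0.26 ± 0.061. For cholesterol synthesis in Old mice, camera gave an adjusted p of 0.0246 (adjusted p = 0.978 with an estimated correlation). None of the 20 myelinating Schwann cell markers passed in the Old mice, over all genes or adjusted over the list alone in limma, with 1 lower at an unadjusted p under 0.05 and 0 of 13 past edgeR, and Pmp2 was at -1.02 ± 0.34. For the Schwann cell list in Old mice, camera gave an adjusted p of 0.0344 (adjusted p = 0.978 with an estimated correlation).

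**Figure D4:**
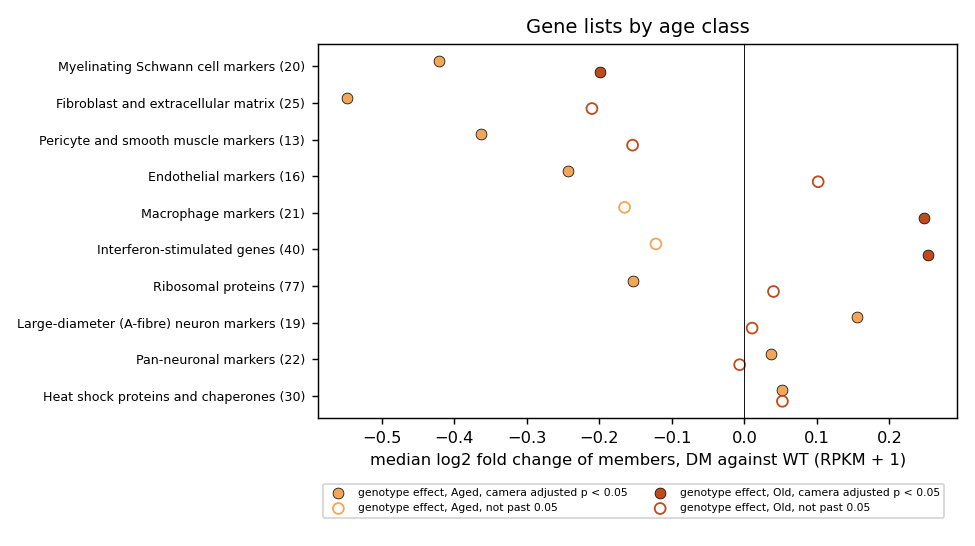
Median log2 fold change of the members of 10 gene lists (y axis, number of members in brackets), double mutant against wildtype, in the Aged (5 against 4) and Old (4 against 4) mice (x axis, log2 of RPKM + 1); filled points passed camera at an adjusted p of 0.05 with a preset correlation, and none passed with an estimated correlation. The fibroblast list lies at -0.55 in the Aged mice, and the interferon list at 0.25 in the Old mice.

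The age comparisons set Old against Aged mice within each genotype, 4 against 4 in the wildtype and 4 against 5 in the double mutant. In the wildtype mice 424 genes rose and 693 fell, and in the double mutant mice 400 rose and 482 fell. Shared between the genotypes were 128 genes that rose and 241 that fell, where 7.42 and 14.6 would be shared if the calls were independent, and 4 genes passed in opposite directions. With edgeR on the partial counts the balance turned, with 892 genes that rose and 522 that fell in the wildtype and 982 and 524 in the double mutant mice, of which 299 and 218 genes also passed on RPKM. Small RNAs gave many of the largest changes. The mitochondrial proline tRNA TrnP was at 1.99 RPKM in wildtype Aged and 66.6 RPKM in wildtype Old mice, a log2 fold change of 4.48 ± 0.38, and the alanine tRNA TrnA rose by 3.61 ± 0.32 (SE, n = 4 each). Bc1, a small non-coding RNA of neuronal dendrites, fell from 1339 to 89.0 RPKM in the wildtype mice (-4.02 ± 0.70). In the double mutant mice it fell by 3.56 on the log2 scale. Genes spanning under 300 bases made up 13 of the 32 wildtype age calls with a log2 fold change of at least 1 in size and 13 of the 28 in the double mutant mice, against 4 of 68 for genotype.

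Other wildtype changes were rises of Mir7009 (3.46 ± 0.18), Snord64 (3.28 ± 0.31) and Cox20, an assembly factor of cytochrome c oxidase (2.70 ± 0.56), and lower values of Mir1291 (-2.22 ± 0.45), the fibroblast gene Pi16 (-1.47 ± 0.34), the serine tRNA TrnS1 (-1.39 ± 0.12) and the nuclear receptor coactivator gene Ncoa7 (-1.33 ± 0.076). In the double mutant mice TrnP (4.47 ± 0.36), Cox20 (3.58 ± 0.53), Snord64 (3.40 ± 0.30), TrnA (3.24 ± 0.30) and Mir7009 (2.95 ± 0.17) rose. TrnS1 (-1.18 ± 0.11), TrnQ (-1.18 ± 0.26), the lymphocyte adaptor gene Sla2 (-1.15 ± 0.22) and TrnE (-1.13 ± 0.13) fell, and edgeR on the partial counts gave 0.13 for Sla2 and, in the wildtype mice, -0.35 for Ncoa7 (adjusted p = 0.720 and 0.600). The age classes differed in read depth and in the ratio of the runs, so age and sequencing could not be separated in these comparisons. In wildtype mice 38.0% of the genes that passed had risen, against 59.7% after centring on the median and 51.5% after TMM rescaling, and without wildtype Aged mouse 4 the count was 565, while without double mutant Old mouse 6 that of the double mutants was 347.

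Many ribosomal protein genes and some respiratory chain genes fell in the older wildtype mice. Of 77 ribosomal protein genes 36 fell and 3 rose, or 52 and 3 adjusted over the list alone, with Rpl10 at -0.56 ± 0.049, Rps3a1 at -1.15 ± 0.10 and Rps7 at 0.57 ± 0.078. For ribosomal proteins in this contrast, camera gave an adjusted p of 5.54e-24 (adjusted p = 0.906 with an estimated correlation). Of 40 nuclear genes of complexes II to V 6 fell, 13 adjusted over the list alone, with Cox6c at -0.66 ± 0.12 and Uqcrb at -0.41 ± 0.082. For complexes II to V, camera gave an adjusted p of 0.000306 (adjusted p = 0.953 with an estimated correlation). Of 36 genes of complex I 1 rose and 2 fell, or 1 and 13 adjusted over the list alone, with Ndufc1 at -0.47 ± 0.086. For complex I, camera gave an adjusted p of 8.63e-05 (adjusted p = 0.953 with an estimated correlation). Of 41 synaptic vesicle genes 9 rose and 1 fell, or 13 and 1 adjusted over the list alone, with Stxbp1 at 0.23 ± 0.040 and Syn2 at 0.24 ± 0.041, against Rab3b at -0.41 ± 0.084. For synaptic vesicle genes with age, camera gave an adjusted p of 3.24e-05 (adjusted p = 0.806 with an estimated correlation).

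Lists of other cell types also passed camera with a preset correlation for age in the wildtype mice. Of 25 fibroblast and matrix genes 1 fell, 4 adjusted over the list alone, with a median log2 fold change of -0.35 (camera adjusted p = 0.000114; adjusted p = 0.953 with an estimated correlation). Of 16 endothelial markers none passed in limma and 3 fell when adjusted over the list alone, with 8 lower at an unadjusted p under 0.05, 2 of 6 that fell in edgeR on the partial counts and a median of -0.21 (camera adjusted p = 0.000563; adjusted p = 0.906 with an estimated correlation). None of the 40 interferon-stimulated genes passed in limma, nor adjusted over the list alone, with 10 lower at an unadjusted p under 0.05, 1 of 20 that fell in edgeR and a median of -0.29 (camera adjusted p = 8.63e-05; adjusted p = 0.953 with an estimated correlation). Of 19 large-diameter neuron markers 4 rose, 5 adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.000306; adjusted p = 0.806 with an estimated correlation). Of 34 potassium channel genes 2 rose by either adjustment (camera adjusted p = 0.00318; adjusted p = 0.906 with an estimated correlation), and of 37 axonal transport and cytoskeleton genes 4 rose, or 6 with 1 that fell adjusted over the list alone (camera adjusted p = 0.0123; adjusted p = 0.906 with an estimated correlation). Markers of tissues that could adhere to the ganglia passed as well. Of 18 adipocyte markers 1 rose by either adjustment, with a median of 0.26 (camera adjusted p = 0.0135; adjusted p = 0.953 with an estimated correlation). None of 24 skeletal muscle markers passed in limma by either adjustment, with 0 at an unadjusted p under 0.05, 0 of 4 past edgeR and a median of 0.20 (camera adjusted p = 0.0194; adjusted p = 0.953 with an estimated correlation). The call of skeletal muscle was lost after TMM rescaling (0.0551) and that of both after centring on the median (0.119 for adipocytes and 0.143 for muscle). Their medians did not shrink, at 0.205 after TMM rescaling and 0.226 after centring for muscle and at 0.291 after centring for adipocytes.

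In the older double mutant mice a few macrophage and inflammation genes rose, while most members of these lists did not pass. Of 21 macrophage markers 2 rose, 5 adjusted over the list alone, the lipid receptor gene Trem2 by 0.72 ± 0.13 and the lysosomal protein gene Cd68 by 0.76 ± 0.15. For macrophage markers, camera gave an adjusted p of 1.62e-05 (adjusted p = 0.957 with an estimated correlation). Of 39 inflammation and complement genes 2 rose, 3 adjusted over the list alone, the complement gene C4b by 0.69 ± 0.13 and the chemokine gene Ccl2 by 1.10 ± 0.26. For inflammation genes, camera gave an adjusted p of 0.00285 (adjusted p = 0.957 with an estimated correlation). Of 27 nerve injury genes 1 rose, 6 adjusted over the list alone, the stress gene Gadd45a by 0.34 ± 0.058. For nerve injury genes, camera gave an adjusted p of 0.00285 (adjusted p = 0.853 with an estimated correlation). Of 33 NRF2 targets and oxidative stress genes 4 rose, over all genes and adjusted over the list alone, with Gstp1 at 0.39 ± 0.045 and the glutathione synthesis gene Gclm at 0.22 ± 0.028. For oxidative stress genes, camera gave an adjusted p of 0.0145 (adjusted p = 0.957 with an estimated correlation).

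Lists of other kinds passed camera for age in the double mutant mice too. None of 24 immediate early genes, which respond to handling of the tissue, passed in limma over all genes and 5 rose adjusted over the list alone, with 8 higher at an unadjusted p under 0.05, 2 of 16 that rose in edgeR and a median of 0.18 (camera adjusted p = 0.00285; adjusted p = 0.957 with an estimated correlation). None of 20 myelinating Schwann cell markers passed in limma by either adjustment, with 0 at an unadjusted p under 0.05, 2 of 13 that rose in edgeR and a median of 0.17 (camera adjusted p = 0.0223; adjusted p = 0.999 with an estimated correlation). Of 17 senescence genes 1 rose, 5 adjusted over the list alone (camera adjusted p = 0.00285; adjusted p = 0.938 with an estimated correlation). None of 40 interferon-stimulated genes passed in limma by either adjustment, with 3 higher at an unadjusted p under 0.05 and 2 of 20 that rose in edgeR (camera adjusted p = 0.0491; adjusted p = 0.999 with an estimated correlation). Lower medians were found for ribosomal proteins, with 5 that rose and 8 that fell, or 6 and 20 adjusted over the list alone (camera adjusted p = 0.0145; adjusted p = 0.999 with an estimated correlation), and for complexes II to V, with 1 and 3, or 2 and 6 (camera adjusted p = 0.0163; adjusted p = 0.999 with an estimated correlation). Of 32 genes of the unfolded protein response 3 fell, 4 adjusted over the list alone (camera adjusted p = 0.0368; adjusted p = 0.938 with an estimated correlation). The calls of the interferon and unfolded protein lists were lost after TMM rescaling (adjusted p = 0.0577 for both).

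The interaction asked whether the genotype effect differed between Old and Aged mice. In limma the signed log2 fold change of double mutant against wildtype was higher in the Old mice for 8 genes and higher in the Aged mice for 1. The balance depended on the scaling, with 6 and 5 genes after centring on the median, and leaving out single mice gave between 2 and 11 genes against between 1 and 6. Ncoa7 was at 41.6 ± 1.14 RPKM in wildtype Aged mice, 16.04 ± 1.63 in wildtype Old, 13.2 ± 1.61 in double mutant Aged and 18.7 ± 0.863 in double mutant Old mice (SD, n = 4, 4, 5 and 4). Its log2 fold change between the genotypes was 0.21 in the Old mice, without passing (limma adjusted p = 0.137), and -1.59 in the Aged mice (limma adjusted p = 6.33e-10), a difference of 1.80 ± 0.10 (SE, limma adjusted p = 4.8e-07). The ribosomal protein gene Rps3a1 was at 30.1 RPKM in wildtype Old mice and between 68.8 and 78.0 RPKM in the means of the other groups (1.13 ± 0.14, limma adjusted p = 0.00637). The remaining named genes were Tpd52l1 (0.80 ± 0.12), the protease inhibitor gene Serpina3g (0.72 ± 0.11) and Fxyd1, a regulator of the sodium pump (0.70 ± 0.099), with limma adjusted p of 0.0216 to 0.0233. Serpina3g was lower in the double mutants in both age classes, by a log2 fold change of -0.86 in Old and -1.58 in Aged mice. LOC105244235 (0.23), LOC105243877 (0.21), D830030K20Rik (0.58) and Gm3629 (-0.32) also passed and are given here although they were chosen after their values were seen. Group means were at most 0.164 RPKM for LOC105244235, 0.294 for LOC105243877 and 0.277 for Gm3629. With a mean RPKM of at least 1 there were 6 genes higher in the Old mice and 0 higher in the Aged mice. The smallest p among other lower values belonged to Mctp2 (-0.32 ± 0.056, limma adjusted p = 0.0746), Kank4 (-0.27 ± 0.048, limma adjusted p = 0.0746), Ginm1 (-0.47 ± 0.085, limma adjusted p = 0.0914), Lgi2 (-0.63 ± 0.13, limma adjusted p = 0.171) and Gpr158 (-0.31 ± 0.065, limma adjusted p = 0.199), none of which passed. Of these, Mctp2, Kank4 and Ginm1 passed after centring on the median (adjusted p of 0.0375 to 0.0475), and Kank4 also after TMM rescaling (0.0413) and with the Schwann cell covariate (0.0367). In contrast, edgeR on the partial counts gave 1 gene that was none of the 9 that passed on RPKM. There Ncoa7 stood at 0.48 and Rps3a1 at 0.0052, while Serpina3g kept its size at 0.72 without passing (adjusted p = 0.404).

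**Figure D5:**
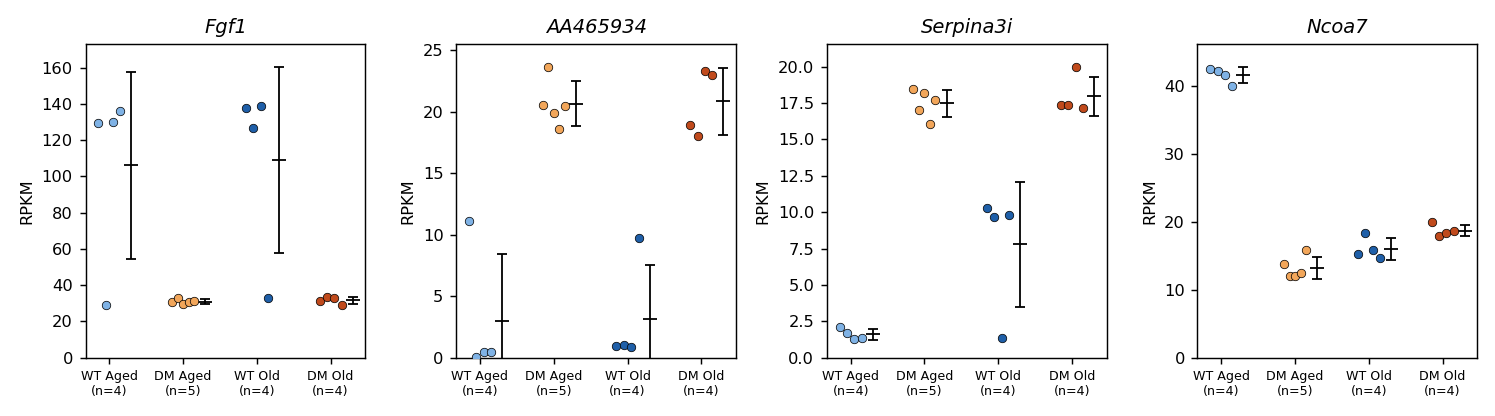
RPKM (y axis) of Fgf1, AA465934, Serpina3i and Ncoa7 in each mouse (points), with the mean and SD of each genotype and age class (n = 4 or 5; bars that would pass below 0 end at the axis). Wildtype mice spread widely for Fgf1, where 2 of them stand at 29.1 and 32.9 RPKM and the other 6 at 127 to 139 RPKM, while Ncoa7 is high in the wildtype Aged mice alone.

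Several gene lists differed in their median genotype effect between the ages by camera with a preset correlation. The 40 interferon-stimulated genes had a median difference between the ages of 0.39 (camera adjusted p = 2.73e-10; adjusted p = 0.647 with an estimated correlation), and none of them passed in limma, nor adjusted over the list alone, with 8 higher at an unadjusted p under 0.05 and 0 of 20 past edgeR. The same genes had a median of -0.29 for age in the wildtype and 0.13 in the double mutant mice. The 21 macrophage markers had a median of 0.51, with Lyz2 at 0.86 ± 0.29 and Cd68 at 0.61 ± 0.22 (camera adjusted p = 2.11e-06; adjusted p = 0.647 with an estimated correlation), and none passed by either adjustment, with 7 higher at an unadjusted p under 0.05 and 0 of 11 past edgeR. The 19 large-diameter neuron markers had a median of -0.17 and none passed by either adjustment, with 5 lower at an unadjusted p under 0.05 and 0 of 16 past edgeR (camera adjusted p = 1.62e-08; adjusted p = 0.152 with an estimated correlation). Among 77 ribosomal protein genes Rps3a1 alone passed, 3 adjusted over the list alone (camera adjusted p = 3.44e-20; adjusted p = 0.647 with an estimated correlation). The 25 fibroblast genes had a median of 0.37 (camera adjusted p = 3.53e-05; adjusted p = 0.723 with an estimated correlation) and the 16 endothelial markers one of 0.25 (camera adjusted p = 4.11e-06; adjusted p = 0.647 with an estimated correlation). The 12 meningeal markers had a median of 0.49 (camera adjusted p = 0.000284; adjusted p = 0.647 with an estimated correlation). The 13 pericyte markers had one of 0.22 (camera adjusted p = 0.0084; adjusted p = 0.753 with an estimated correlation) and the 20 myelinating Schwann cell markers one of 0.22 (camera adjusted p = 0.00489; adjusted p = 0.839 with an estimated correlation). No gene of these 5 lists passed in limma or edgeR over all genes, with 5, 5, 2, 1 and 1 higher at an unadjusted p under 0.05 in this order, and 1 endothelial marker passed adjusted over the list alone. Over the 6 contrasts camera called 10, 5, 16, 12, 11 and 16 of the 53 lists, in the order both ages, Old, Aged, age in wildtype, age in double mutant and interaction. None of these calls held with an estimated correlation.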

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

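The tests of the region around Pink1, of near-identical gene copies and of the spread of Snca were chosen only after the results were seen; those of neighbouring genes, of sequencing and of other splits of the mice were chosen before.

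The gene count of each contrast was compared with that of other splits of the same mice. For 5 contrasts every other split gave fewer genes than the real one, which argues against chance. These were the genotype effect over both ages (3381 genes, highest other split 3), in Old mice (1082, highest other 10) and in Aged mice (2037, highest other 322). The others were the age effect in wildtype (1117, highest other 18) and double mutant mice (882, highest other 19). For Old mice and for age in wildtype mice only 35 splits exist, so the real one being 1 of 35 is the most they can show. The splits speak only to random regrouping of the mice, and not to differences in background or sequencing. For the interaction, 5 of 100 splits, the real one included, gave at least its 9 genes and the highest other gave 184, so these splits do not exclude chance. They are no clean test of it, because they carry age differences into this term, which points to a structure of the samples. All 5 splits that kept or exchanged the age class of all 8 wildtype mice gave 5 to 184 genes, against 0 to 21 in the other 94, although the 2 that kept all 9 double mutants gave 0. A test chosen after these results were seen exchanged between mice what genotype and age class left unexplained, and 99 such exchanges gave at most 2 genes.

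The first pattern is the set of genes that changed by at least 1 on the log2 scale between genotypes. It holds 67 genes on nuclear chromosomes, Pink1 included and each Entrez number counted once. A passenger region kept from the strain in which Pink1 was targeted is argued against as the whole cause, since 7.46% of them lie within 20 Mb of Pink1. That share exceeds the 2.91% of all genes that lie there (two-sided Fisher's exact p = 0.0453). However, it counts Pink1 itself and Mir7019, which lies within Pink1, so this p rests partly on the targeted gene. Of all genes there 21.7% passed against 14.6% elsewhere (two-sided Fisher's exact p = 1.25e-06), so a part from this region stays open. Reads shared between near-identical copies may contribute, since 65.7% are predicted genes or have a family member within 1 Mb, against 40.02% of the genes that did not pass, although among all genes that passed the share was 35.3%. Background haplotypes that differ between the lines stay open: genes that changed by at least 0.5 formed 38 neighbouring pairs, above the highest of 1000 shuffles (13), and 12 pairs of named genes of different families, against a highest of 9. For age in wildtype mice these were 4 pairs, equal to the highest shuffle, and 2 against a highest of 3. The first 10 Mb of chromosome 14 alone held 25 of the 67 genes that changed by at least 1, nearly all predicted genes, which may also share reads. The ratio to the shuffled mean, set beforehand as the measure, was 7.72 for genotype and 8.10 for age on those few pairs, so by it the haplotypes cannot be told apart from ordinary clustering. The age comparison is no clean yardstick, since wildtype mice also differed among themselves. Wildtype Old mouse 1 stood within the double mutant range for Tekt2 (0.548 RPKM, range 0.42 to 0.923) and LOC105244693 (5.43, range 4.09 to 6.675). So did 2 wildtype mice for Fgf1. All these mice had wildtype levels of Pink1, so these genes can reach that level without its loss. For most genes named over both ages, all 9 double mutant mice lay outside the wildtype range. An effect of the engineered genes themselves is also open and untested, since the design has no single mutants or littermates in the labels.

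The second pattern is the age effect in wildtype mice, with 1117 genes. If it were age, mice of 62 weeks might already differ from mice of 41 weeks in the same direction, but across the 958 of these genes with a mean RPKM of at least 1 the correlation was 0.0483, and the other pairings of the same 4 mice gave 0.325 and -0.104. Among all 9 Aged mice, limma called 0 genes for 60 to 62 against 41 weeks, with 932 at an unadjusted p under 0.05. Age and separate sequencing of the age classes cannot be told apart, because every Old mouse has a run ratio of 1.01 to 1.02 and every Aged mouse one of 1.05 to 1.06. A biological change after 62 weeks stays open and untested. So does a difference in background between the wildtype mice of the age classes. Serpina3i was at 1.36 RPKM in wildtype Old mouse 4 and 9.67 to 10.3 in the other wildtype Old mice, against 1.28 to 2.09 in the wildtype Aged mice.

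The third pattern is the spread of Snca among double mutant mice, from 13.4 to 41.3 RPKM against 9.86 to 12.9 RPKM in wildtype mice. The partial counts, with 2.79% of the implied Snca reads, did not show it. The double mutant Aged mice at 35.6 and 41.3 RPKM had 4.55 and 5.96 CPM, and the other double mutant Aged mice had 4.28 to 6.29 CPM. A varying share of neurons is argued against as its cause, since the mean of the pan-neuronal markers ranged over only 4.88% of the log2 range of Snca. A change of the chromosomal region around the mouse Snca gene is likewise argued against, since the 5 expressed genes within 2 Mb ranged over a median of 12.3%. The insertion site of the transgene is not in the tables used here, so this test cannot speak for the region around the transgene. Transgene copy number or expression could vary between mice, and neither was tested, since the sequence of the transgene is not in the tables used here.

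Single mice stood far from the rest of their group in 24 of 188 groups of values, where chance gives about 5%. In Fgf1 these were wildtype Aged mouse 2 at 29.1 RPKM (others 129 to 136) and wildtype Old mouse 6 at 32.9 (others 127 to 139). In AA465934 they were wildtype Aged mouse 1 at 11.1 RPKM (others 0.062 to 0.438) and wildtype Old mouse 6 at 9.75 (others 0.864 to 1.02). Wildtype Old mouse 4 was apart in 3 neighbouring genes, with Serpina3i at 1.36 RPKM (others 9.67 to 10.3), Serpina3f at 0.859 (others 3.78 to 4.15) and Serpina3g at 40.3 (others 29.9 to 31.3). Wildtype Old mouse 1 had Mir7019 at 5.69 RPKM (others 0.209 to 0.406) and Prnp at 129 (others 143 to 146), and wildtype Old mouse 3 had Ccl27a at 1.49 RPKM (others 1.24 to 1.28) and Mir7009 at 15.2 (others 10.6 to 11.2). Wildtype Old mouse 6 had TrnA at 84.8 RPKM (others 45.2 to 50.9) and Mir1291 at 0.018 (others 0.231 to 0.253). Pink1 was at 114 RPKM in wildtype Aged mouse 3 (others 123 to 124), which also had Mir344b at 0.002 RPKM. Wildtype Aged mouse 4 had Mir6982 at 0.022 RPKM (others 0.291 to 0.325) and Mir1291 at 0.392 (others 7.33 to 8.11). Snord64 was at 2.37 RPKM in wildtype Aged mouse 2 (others 0.021 to 0.150), and Cox20 was at 10.1 RPKM in wildtype Aged mouse 1 (others 0.002 to 0.409). Among double mutant mice, Mir344b was at 0.021 RPKM in Aged mouse 1, Cox20 at 0.628 in Aged mouse 2 (others 0.002 to 0.037), Serpina3i at 19.95 in Old mouse 5 (others 17.1 to 17.4) and LOC105244693 at 4.09 in Old mouse 4 (others 5.46 to 5.56). Bc1 was at 662 RPKM in double mutant Old mouse 5 (others 32.2 to 58.1).

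The genotype effect differed between Old and Aged mice for 9 genes by the interaction term in limma. The difference, Old minus Aged on the log2 scale, was 1.80 for Ncoa7, 1.13 for Rps3a1, 0.80 for Tpd52l1, 0.72 for Serpina3g, 0.70 for Fxyd1, 0.58 for D830030K20Rik, 0.23 for LOC105244235, 0.21 for LOC105243877 and -0.32 for Gm3629. LOC105244235, LOC105243877 and Gm3629 had group means of at most 0.294 RPKM. For some of the 9 genes mainly the wildtype mice shifted between the age classes. From Aged to Old the log2 change was -1.15 in wildtype and -0.023 in double mutant mice for Rps3a1, and -0.72 and 0.078 for Tpd52l1. For Ncoa7 (-1.33 and 0.47) and Serpina3g (-0.36 and 0.36) both genotypes moved. Age and sequencing cannot be told apart and background was not tested, so the term need not reflect age.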

How the results depend on the processing

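The rescalings by TMM factors and by the median, the omission of genes under 300 bases and the Schwann cell covariate were chosen after seeing the data. Under the first 3 of these, and with a pseudocount of 0.1 or only genes with a mean RPKM of at least 1, every gene count stayed within 1.5 times its value, and the agreement of the age classes stayed between 0.603 and 0.669. Of the values of named genes under all alternatives, 2079 kept direction and side of the threshold, 100 lost the threshold, 10 gained it and 34 turned direction. Some of the 100 were values to which DESeq2 gave no adjusted p, among them those of AA465934 and Bc1, and these were counted as lost. The causes of the changes below were not tested.

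With only the groups compared, 476 genes passed in Old mice, 388 for age in wildtype and 346 for age in double mutant mice. Calls ended there for Mir344b in Old mice (adjusted p = 0.169), Cox20 (0.107), Mir1291 (0.0985) and Pi16 (0.0636) in wildtype age and Bc1 in double mutant age (0.0681). A block for mouse number gave 2006 genes over both ages, 403 in Old and 957 in Aged mice, and Xist stood at -0.031; mice of the same number did not resemble each other (mean r -0.0695 over 7 pairs against 0.0168 over 29 others), so the block is arbitrary. It ended AA465934 (0.126), Mir1291 (0.120) and Mir344b (0.104) in Old mice. With 1 surrogate variable 6 lists passed and Xist stood at -0.059. With an estimated correlation 0 lists passed, and 2 passed with fry. The Schwann cell covariate gave 1639 genes over both ages and 962 in Aged mice, and 10 lists, 8 upward and 2 downward, of which only large-diameter neuron and mast cell markers were among the 10 lists without it.

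Over the fits of partial counts named calls ended, or had no adjusted p in DESeq2, 62 times with the direction kept. Among those that ended were Folh1, Zfp949 (no filter), Snca and Ncoa7, and those of Fgf1, Sla2 and Rps3a1, given below, ended with the direction turned. With no filter and in DESeq2, Zfp949 stood at -0.68 and -0.45, and DESeq2 gave it no adjusted p. Calls also ended there for Dnase1l3 (2.22 and 2.35) and LOC101055754 (-1.80 and -1.95) over both ages and Psmc3ip in Aged mice (-2.35 and -2.52), at adjusted p of 0.103 to 0.185. Genes over both ages numbered 1050 (edgeR), 1049 (RLE factors), 1399 (no low-count filter), 678 (run 1), 648 (run 2), 948 (voom) and 1095 (DESeq2). In the same order Old mice gave 383, 387, 640, 262, 252, 486 and 444, and Aged mice 519, 525, 782, 325, 297, 338 and 556. Age in double mutant mice gave 1506, 1534, 1547, 1399 and 1519 with edgeR, RLE factors, no filter, voom and DESeq2. The interaction gave 1, 1, 42, 1, 1, 2 and 1 genes. With voom 3 lists passed, and with DESeq2 the agreement of the age classes was 0.230.

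Xist, not past the threshold on RPKM, stood at -0.18 with edgeR, RLE factors, no filter, run 1, voom and DESeq2 and at -0.19 with run 2. Fgf1 stood at 0.044 with edgeR, 0.042 with RLE factors, 0.043 with no filter, 0.0080 with voom and 0.044 with DESeq2. Sla2 in the double mutant age effect stood at 0.13, 0.12, 0.13, 0.020, 0.25, 0.13 and 0.11 in the order of the counts above. For the interaction Rps3a1 stood at -0.067 with run 1 and -0.016 with voom, Kank4 at 1.06 with no filter and 1.16 with DESeq2, and Lgi2 at 3.29 and 2.27.

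Leaving out each mouse in turn gave 2774 to 3552 genes over both ages, 783 to 1168 in Old, 1391 to 2206 in Aged mice, 565 to 1211 for age in wildtype, 347 to 1089 for age in double mutant mice, 4 to 17 for the interaction, 5 to 15 lists and an agreement of 0.587 to 0.643. Age in wildtype mice gave 589 and 683 without wildtype Old mice 4 and 6, and 741, 736 and 565 without wildtype Aged mice 1, 2 and 4. Age in double mutant mice gave 575 and 347 without double mutant Old mice 4 and 6, and 467 and 522 without double mutant Aged mice 3 and 4. The interaction gave 14, 16, 17 and 4 without wildtype Old mice 1, 3, 4 and 6, 4, 15 and 16 without wildtype Aged mice 1, 3 and 4, and 4 without double mutant Old mice 1 or 6 or double mutant Aged mouse 3. The lists numbered 5 without wildtype Aged mouse 4 or double mutant Old mouse 4, and 6 without double mutant Old mouse 6. Xist stood between -0.025 and 0.040, at -0.016, -0.011, -0.017, -0.011, -0.012, -0.0050 and -0.025 without wildtype Old mouse 1 or 3, wildtype Aged mouse 1 or 4, double mutant Old mouse 1 and double mutant Aged mouse 3 or 5. Named calls ended for AA465934 in Old mice without wildtype Old mouse 4 (adjusted p = 0.0531), and for Pi16 without wildtype Aged mouse 4 (0.0707), wildtype Old mouse 3 (0.0532) or 6 (0.0672). That of TrnQ ended without double mutant Aged mouse 3 (0.0503) or Old mouse 6 (0.0747). In the interaction Fxyd1 ended without any of 3 mice, Tpd52l1 of 5 and Serpina3g of 10, at adjusted p of 0.0526 to 0.0633. Mctp2 passed without wildtype Old or Aged mouse 4 (0.0436 and 0.0415), Kank4 without wildtype Aged mouse 4 (0.0288) or double mutant Aged mouse 5 (0.0493) and Ginm1 without double mutant Old mouse 5 (0.0397). Mir1291 over both ages also ended with no age term, the block, the surrogate variable and the Schwann cell covariate (adjusted p of 0.0526 to 0.138), and Mir6982 with the last 2 of these (0.0704 and 0.157). The call of Mir1291 ended as well on the partial counts, at 0.45 in edgeR with no filter and 0.48 in DESeq2 (adjusted p = 0.777 and 0.775).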

Other observations

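The gene lists of this part were fixed in advance, and the count of genes along chromosome 14 was chosen only after the result was seen. Genes of excitability and itch changed in both directions between the genotypes over both ages (log2 fold change ± SE, limma). Over all 22861 genes 1652 rose and 1729 fell, so some members of most lists would pass. Whether these lists hold a larger share of changed genes was not tested. Of 28 thermosensory and mechanosensory channel genes 3 rose and 1 fell, over all genes and adjusted over the list alone, with the acid-sensing channel genes Asic1 at 0.36 ± 0.046 and Asic3 at 0.21 ± 0.049, the potassium leak channel gene Kcnk4 at 0.21 ± 0.047 and the irritant receptor gene Trpa1 at -0.35 ± 0.083 (camera adjusted p = 0.192). Of 34 voltage-gated potassium channel genes 4 rose and 4 fell by either adjustment, with Kcng4 at 0.50 ± 0.076 and Hcn2 at 0.22 ± 0.044 against Kcnc4 at -0.65 ± 0.082 (camera adjusted p = 0.933). Of 9 itch neuron markers 4 rose and 1 fell by either adjustment, with the interleukin 31 receptor gene Il31ra at 1.23 ± 0.16, its partner Osmr at 0.38 ± 0.087, Htr1a at 0.48 ± 0.079 and Sst, which encodes somatostatin, at -0.48 ± 0.10 (camera adjusted p = 0.0999). Of 14 peptidergic nociceptor markers 1 rose and 2 fell, or 1 and 3 adjusted over the list alone, with Oprk1, the kappa opioid receptor gene, at 0.31 ± 0.049 and Tac1, the substance P precursor gene, at -0.21 ± 0.058 (camera adjusted p = 0.738). Of 11 markers of C-fibre touch neurons 3 fell, or 3 with 1 that rose adjusted over the list alone, with Slc51a at -0.64 ± 0.083 and Rarres1 at -0.40 ± 0.062 (camera adjusted p = 0.091). None of these lists passed with an estimated correlation.

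Lipid signalling and lysosomal genes also changed in both directions, and their counts were likewise not tested against the share over all genes. Of 27 endocannabinoid and bioactive lipid genes 3 rose and 2 fell by either adjustment, with the cannabinoid receptor gene Cnr1 at 0.59 ± 0.078 and Napepld, an enzyme of anandamide synthesis, at 0.17 ± 0.036 against the lipoxygenase gene Alox12 at -0.34 ± 0.059 (camera adjusted p = 0.662). Of 49 sphingolipid genes 7 rose and 8 fell, or 9 and 9 adjusted over the list alone, with Degs1 at 0.15 ± 0.025 and the acid sphingomyelinase gene Smpd1 at -0.18 ± 0.030 (camera adjusted p = 0.933). Of 40 lysosomal genes 6 rose and 5 fell by either adjustment, with Cln5 at -0.39 ± 0.040 and the cholesterol transporter gene Npc1 at -0.27 ± 0.041 (camera adjusted p = 0.714). Of 13 satellite glia markers 3 rose and 3 fell, or 3 and 4 adjusted over the list alone, with the glutamine synthetase gene Glul at 0.38 ± 0.056 and the endothelin receptor gene Ednrb at -0.59 ± 0.11 (camera adjusted p = 0.999). Of 33 NRF2 targets 1 rose and 9 fell, or 2 and 9 adjusted over the list alone, with Gsta4 at -0.54 ± 0.062 and the catalase gene Cat at -0.12 ± 0.018 (camera adjusted p = 0.0863). Markers of tissues that could adhere to the ganglia did not pass as lists for genotype over both ages, with camera adjusted p of 0.143 for skeletal muscle, 0.53 for adipocytes, 0.494 for spinal cord cells, 0.933 for bone and cartilage, 0.998 for erythroid cells and 0.0863 for meninges. The meningeal list passed within the Aged mice, where 2 of 12 fell, by either adjustment, with a median of -0.38 (camera adjusted p = 0.00166; adjusted p = 0.653 with an estimated correlation).

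The start of chromosome 14 held many changed genes. From 0 to 5 Mb 26 of 28 genes passed for genotype over both ages, and from 5 to 10 Mb 43 of 56 passed, many of them predicted genes with Gm or LOC symbols, beside Dnase1l3, LOC101055754, LOC100861615 and LOC102638110. The sign of a list's median, mean and test differed for the Parkinson's disease genes (median 0.0022, mean -0.15, camera downward), since Pink1 dominates their mean, and fry, which asks only whether a list moves one way, gave that list an adjusted p of 2.33e-09. It also differed for the potassium channels (median -0.0055, camera upward), the bone and cartilage markers (median 0.0021, camera downward) and the cold-sensing neuron markers (median 0.028, camera downward).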
